A study of Mus musculus with 6 samples.

How the data were processed

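Messenger RNA was measured in 6 samples labelled as aortic smooth muscle cells of mice, 3 WT and 3 with a floxed miR-21 gene and the smooth muscle Cre driver, all 30 weeks old and fed a western diet for 20 weeks. Per the labels' protocols, tissue was frozen, RNA was taken up in Trizol, and libraries were made from 1 ug of total RNA with an Illumina TruSeq RNA kit.

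The authors deposited 1 table of estimated counts per gene for all 6 samples. Per the submitters' processing notes, the build was mm10, and STAR 2.6 and DESeq2 were used, with no role given. The counting tool and the annotation are not given in the sources used here. The deposited expected counts are not normalized, and 43.6% to 54.3% of the values in a library are exactly whole numbers. Estimated counts share reads among similar genes, so pseudogenes, paralogs and overlapping genes are uncertain. They were rounded to whole numbers before every count test. Columns were assigned to samples by the sample code in the column name, and 0 per-sample columns were left without a sample. The table lists 22956 genes, of which 23 had symbols turned into dates.

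Library totals ranged from 37787465 to 154384307 estimated counts, a ratio of 4.09. TMM factors lay between 0.987 and 1.02. The median standard error of a log2 fold change was 0.136 and the median 95% interval reached 0.323 to either side. Intervals cover the spread between these 6 libraries. Replicate pairs of a group differed beyond counting noise (mean chi-square per gene 31.4 to 111), so none was treated as 1 library deposited in 2 columns.

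The comparison was knockout against WT. Genes were kept by edgeR's filterByExpr (16654 genes), scaled by TMM and tested with the robust quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are TMM-scaled. In all, 33 gene lists were fixed before the data were examined, and the 30 lists with at least 3 tested members were tested on voom values with camera of limma 3.58.1, with a preset correlation of 0.01 and also with an estimated one. The directional and mixed tests of fry were run beside it. Named genes followed a rule also fixed before the data were examined. It took Mir21a and Vmp1, and up to 10 changed genes per direction filled up to 6 by smallest p among genes with mean log2 CPM of at least 2. From each list past its threshold it took the 3 members with the smallest p in the direction of the list. It also took 12 contractile, modulated and target genes chosen beforehand. Predicted genes were left out of the genes picked by p, and 3 genes that the rule names are not reported here.

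For the site test, 3′ UTRs of GENCODE M21 (GRCm38, the same assembly as mm10) were searched for ATAAGCT and ATAAGCTA, the matches to miR-21-5p, UAGCUUAUCAGACUGAUGUUGA. Of the genes in the table, 21548 matched this annotation by position once the end coordinate was lowered by 1, 1347 matched by symbol and 61 did not match. For each gene the transcript with the best APPRIS principal tag was used, with a 3′ UTR of at least 8 bases. Sites were permuted 100000 times within 25 bins of UTR length and mean expression. Genes with only TAAGCTA, the longer site without its first base, counted as genes without a site. The site score per library used log2 of CPM plus 0.1.

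Alternatives were DESeq2 size factors, upper-quartile factors, no low-count filter, at least 1 CPM in 3 samples, DESeq2 1.42.0, limma-voom with sample quality weights, the replicate number as a block, leaving out each library, an FDR of 0.1, a 2-fold minimum, the longer site alone and the longest UTR. Thinning to the smallest library and 1 surrogate variable (sva 3.50.0) were chosen after seeing the data. Permutations, windows and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

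The count test was tested on simulated data drawn from the real means, library sizes and dispersions of 16654 genes with 200 changed genes. For knockout against WT it recovered 23.9% of 67 genes changed 1.5-fold, 70.1% of 67 changed 2-fold and 93.9% of 66 changed 4-fold, with 5 false calls. The list test recovered a simulated 1.3-fold shift of 1 list of 23 genes and called 1 other list. Genes were drawn independently there, so it does not give the false calls for lists whose members move together. The site test was run on 13172 genes with fold changes drawn as independent normal noise, not from counts. It gave a permutation p of 0.569 with no simulated shift, and returned shifts of 0.0765 and 0.110 where 0.05 and 0.1 had been put in.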

Results

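RNA was sequenced from 6 samples labelled as aortic smooth muscle cells of C57B6 mice, 30 weeks old, after 20 weeks of a western diet, a high-fat feed used to bring on atherosclerosis. Of these samples, 3 were wild type (WT) and 3 came from animals whose floxed miR-21 gene can be deleted in smooth muscle by an inducible Cre driven from the Myh11 promoter (miR-21 knockout). Both genotypes carried mTmG, a reporter that switches colour in cells where Cre has acted. miR-21 is a microRNA, a short RNA that lowers the messages whose 3′ untranslated regions (UTRs) pair with its seed. The total estimated count was 37996254 in WT 1, 39938913 in WT 2 and 154384307 in WT 3. It was 37787465 in knockout 1, 43708404 in knockout 2 and 72277179 in knockout 3. No label states whether the replicates are separate animals, so p-values of tests between the libraries measure only the spread between these samples, which could be technical. Tests that compare genes with genes, such as the permutation of sites, do not measure that spread. The question was which messages differ between smooth muscle with and without miR-21 after the same diet.

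The targeted gene could not be checked from these counts. Mir21a lies on chromosome 11 from 86584067 to 86584158 on the minus strand (mm10), inside the last exon and 3′ UTR of the overlapping gene Vmp1, and its own level was not analysed here. Vmp1, a membrane protein gene of autophagy (chromosome 11, 86583865 to 86683836), had 69.7 ± 15.3 CPM (counts scaled to the library total) in WT and 68.1 ± 8.12 CPM in the knockout (SD, n = 3 each). Its log2 fold change, knockout over WT, was -0.03 ± 0.16 (SE). Counts over the whole of Vmp1 check nothing about the loss of the microRNA.

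Messages with a miR-21 site lay higher in the knockout. Of the 13172 genes whose 3′ UTR was searched, 941 held the sequence ATAAGCT, the match to the miR-21-5p seed, and their median log2 fold change was 0.05. The 12231 genes without a site had a median of -0.01. The difference was 0.0569, against a mean of 0.0257 when sites were permuted among genes of like UTR length and expression (permutation test, two-sided, p = 1e-05, the smallest the permutations can give). Genes are not independent replicates in this test. The 280 genes with the longer site ATAAGCTA, which ends in an additional A, differed from genes without a site by 0.0982. Permuted sites gave a mean of 0.0292 there (permutation p = 1e-05, again the smallest possible). Fold changes were above 0 in 63.1% of genes with a site, in 71.8% of those with the longer site and in 48.3% of genes without one. Of the genes with a site, 80 were higher and 14 lower at an unadjusted edgeR p under 0.05, against 528 and 289 of those without. These shares and counts are not corrected for UTR length or expression.

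In each library, a site score was taken as the median centred log2 CPM of genes with a site minus that of genes without. It was -0.011, -0.026 and -0.054 in WT 1, 2 and 3, and 0.025, 0.040 and 0.025 in knockout 1, 2 and 3. The mean was -0.030 ± 0.022 in WT and 0.030 ± 0.009 in the knockout (SD, n = 3 each), a difference of 0.060. The score is not corrected for UTR length or expression. All knockout libraries lay above all WT libraries, and the exact permutation test gave p = 0.1 (two-sided), the smallest that 3 against 3 allows.

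**Figure D1:**
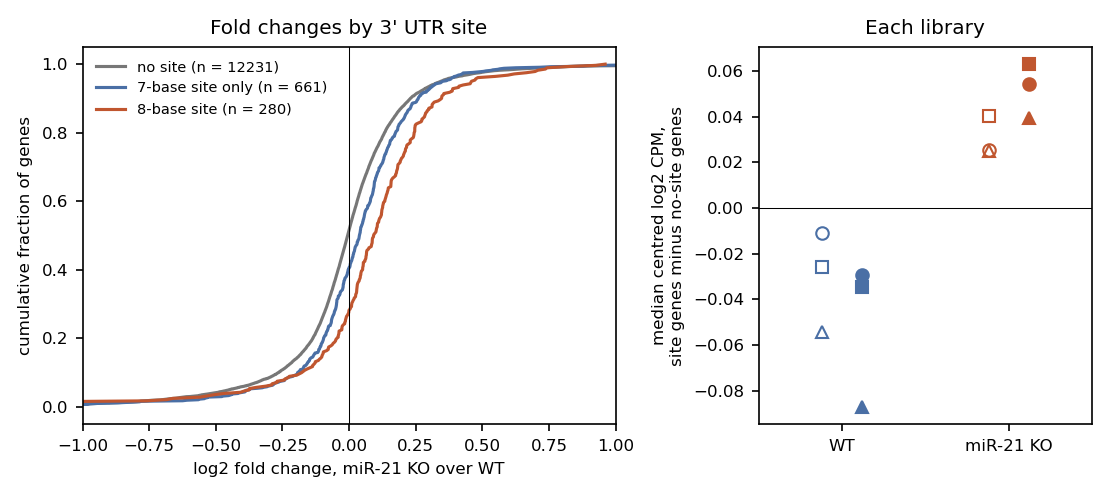
Left, cumulative fraction of genes (y) against log2 fold change, knockout over WT (x), for genes with no site, a 7-base site only or an 8-base site. Right, the site score of each library on the log2 scale, open symbols for all sites and filled symbols for 8-base sites, with circles, squares and triangles for replicates 1, 2 and 3. The lowest knockout score for all sites was 0.025 and the highest WT score was -0.011.

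No single gene passed the threshold over all genes. Of 16654 genes tested with edgeR's quasi-likelihood test, 0 had a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 0.217. At an unadjusted p under 0.05, 658 genes were higher and 335 lower in the knockout, where 832 would be reached by chance. DESeq2's Wald test, run on the same counts, called 60 genes higher and 15 lower at an adjusted p under 0.05. With upper-quartile scaling the unadjusted counts were 538 higher and 415 lower. Without knockout 1 they turned to 769 higher and 956 lower, without knockout 2 they were 414 and 178, and without WT 2 they were 798 and 581.

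Among the genes with the smallest p on the higher side, Reck, a membrane-anchored inhibitor of matrix metalloproteinases (chromosome 4, 43875530 to 43944806), had 140 ± 2.19 CPM in WT and 222 ± 17.6 CPM in the knockout (SD, n = 3 each). Its log2 fold change was 0.67 ± 0.08 (SE), with an edgeR adjusted p of 0.217 and a DESeq2 adjusted p of 7.9e-10, the lowest over the alternatives, which reached 0.978. All 3 knockout libraries lay above all 3 WT libraries. Cdip1, a regulator of apoptosis (chromosome 16, 4750348 to 4790292), had 42.8 ± 2.19 CPM in WT and 64.7 ± 1.24 CPM in the knockout. Taf7, a subunit of the general transcription factor TFIID, went from 8.58 ± 1.24 to 16.3 ± 1.35 CPM. Spg20, which encodes spartin, had 68.7 ± 10.03 CPM in WT and 115 ± 5.71 CPM in the knockout. Kif1a, a kinesin motor gene, and C2cd3, a centriole gene, had log2 fold changes of 0.52 ± 0.07 and 0.53 ± 0.08 (SE). Reck, Cdip1, Taf7 and Spg20 each hold the longer miR-21 site, and Kif1a and C2cd3 do not hold ATAAGCT. None of these 6 genes passed the edgeR threshold, and all 6 passed that of DESeq2.

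On the lower side, Moxd1, a monooxygenase-like gene (chromosome 10, 24223517 to 24302790), had 10.2 ± 1.31 CPM in WT and 0.480 ± 0.424 CPM in the knockout (SD, n = 3 each), a log2 fold change of -4.47 ± 0.54 (SE). Its edgeR adjusted p was 0.374 with all libraries and 0.0126 without knockout 1, where Moxd1 was the 1 gene called. Over the alternatives Moxd1 had adjusted p from 3.3e-20 in DESeq2 to 0.978. Folh1, a glutamate carboxypeptidase gene, had 9.38 ± 3.03 CPM in WT and 2.71 ± 1.19 CPM in the knockout. Atp1b1, a subunit of the sodium pump, had 61.4 ± 7.93 CPM in WT and 35.6 ± 6.94 CPM in the knockout. Kcnj8, a subunit of the ATP-sensitive potassium channel of vascular muscle, had a log2 fold change of -0.50 ± 0.10 (SE). Mrps23, of the mitochondrial ribosome, and Scpep1, a serine carboxypeptidase, had log2 fold changes of -0.45 ± 0.07 and -0.56 ± 0.12 (SE), and both lie on chromosome 11 within 2.5 Mb of Mir21a.

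Of the fixed list of reported miR-21 targets, 20 of 27 tested members were higher in the knockout, and the list passed camera with a preset correlation of 0.01 (adjusted p = 0.0014 over 30 lists). Its adjusted p was 0.516 with an estimated correlation and between 6.5e-08 and 0.0170 in the other alternatives. Over all genes 0 members passed the edgeR threshold, and 4 passed when adjusted over the list alone. These were Reck (adjusted p = 0.0014), Cdc25a, a cell-cycle phosphatase (0.0126), Ski, a repressor of TGF-beta signalling (0.0126), and Dusp8, a MAP kinase phosphatase (0.0133). Dusp8 was named after its values were seen. Ski had 358 ± 13.03 CPM in WT and 455 ± 4.10 CPM in the knockout, and Cdc25a 14.7 ± 1.21 and 20.4 ± 1.19 CPM (SD, n = 3 each). The reported targets Pdcd4, Spry1 and Timp3 differed by less than the spread between libraries. The log2 fold change of the translation inhibitor Pdcd4 was 0.03 ± 0.15, of Spry1 0.25 ± 0.19 and of Timp3 0.16 ± 0.21 (SE). The sign of Pdcd4 turned under limma-voom with sample weights (-0.02), without WT 1 (-0.11) and without knockout 3 (-0.04), that of Timp3 turned without knockout 1 (-0.11), and Spry1 was at 0.42 without WT 1 and at 0.14 without WT 3. In the directional test of fry, which asks whether the members of a list move one way without comparing them with other genes, 0 of the 30 lists passed. The smallest adjusted p was 0.0702, for the miR-21 targets and the TGF-beta and BMP genes, and it was 0.350 for the MHC class II genes and 0.817 for the other 7 lists that passed camera with the preset correlation. In fry's mixed test, which takes changes in either direction, the miR-21 targets alone passed (adjusted p = 2.9e-05).

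**Figure D2:**
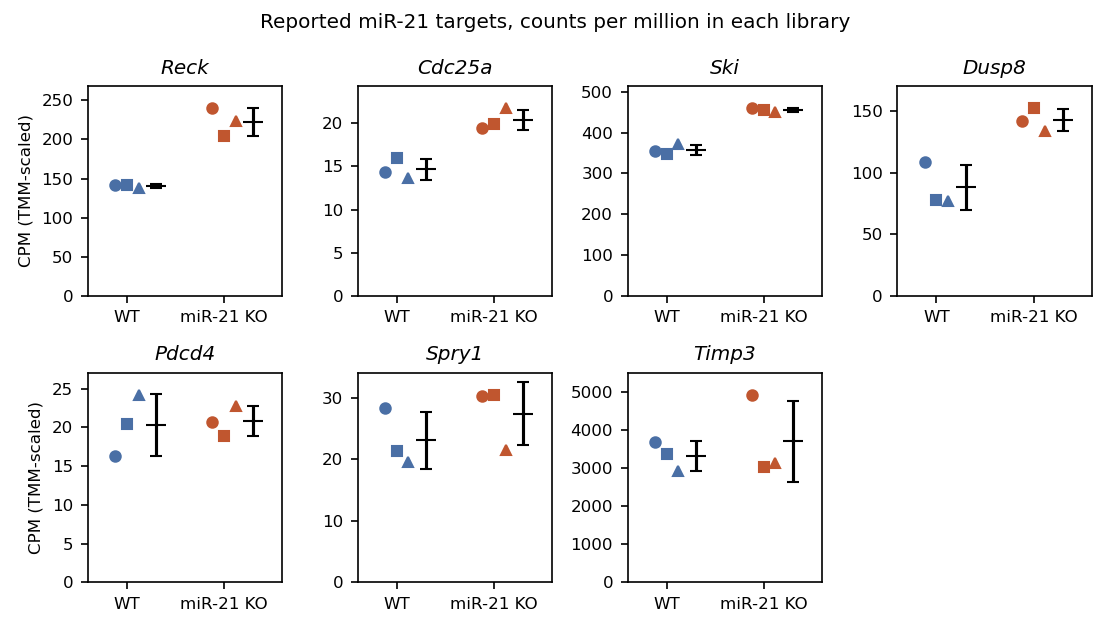
CPM after TMM scaling (y) of 7 reported miR-21 targets in each library, with circles, squares and triangles for replicates 1, 2 and 3, and the horizontal bar and whiskers for the mean ± SD (n = 3 each). Reck lay between 137.7 and 142 CPM in WT and between 204 and 239 CPM in the knockout, while the groups overlapped for Pdcd4, Spry1 and Timp3.

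Genes of the contractile state of smooth muscle were mostly higher, and genes of the modulated, matrix-forming state mostly lower. Of 25 contractile genes, 22 were higher (preset camera adjusted p = 0.0465; adjusted p = 0.822 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. At an unadjusted edgeR p under 0.05, 2 of the contractile genes were higher and 1 was lower. Flna, an actin crosslinker, had a log2 fold change of 0.41 ± 0.17, Myocd, a coactivator of contractile genes, 0.36 ± 0.15, and Synpo2 0.28 ± 0.16 (SE). Myh11, Acta2, Tagln and Cnn1 had values of 0.29 ± 0.19, 0.18 ± 0.20, 0.05 ± 0.15 and 0.08 ± 0.21. Without WT 1 Myh11 was at 0.14, Acta2 at 0.03 and Cnn1 at -0.07, and without WT 2 they were at 0.43, 0.35 and 0.24. Cnn1 was at -0.04 without knockout 2, Tagln at -0.06 without WT 1, Synpo2 at 0.13 without knockout 2 and Myocd at 0.23 without WT 3. Of 20 modulated genes, 16 were lower (adjusted p = 0.0328; adjusted p = 0.822 with an estimated correlation). S100a4 had -0.34 ± 0.14, Ly6a -1.26 ± 0.65, the proteoglycan gene Lum -0.92 ± 0.62, Spp1 -0.49 ± 0.74 and Lgals3 -0.33 ± 0.32, and Fn1 was at 0.01 ± 0.33 and turned sign with upper-quartile scaling (-0.01). Of 16 osteochondrogenic genes, 10 were lower (adjusted p = 0.033; adjusted p = 0.822 with an estimated correlation), among them Comp at -0.99 ± 0.50, Alpl at -0.30 ± 0.25 and Sox9 at -0.19 ± 0.22. Lum was at 4108, 1673 and 3577 CPM in WT 1, 2 and 3 and at 3130, 706 and 1099 CPM in knockout 1, 2 and 3, so that WT 2 lay beside the knockout and knockout 1 beside WT. Without knockout 1 the log2 fold changes of Lum, Spp1 and Lgals3 were -1.80, -1.66 and -0.72, and without knockout 2 they were -0.56, -0.07 and -0.12. Ly6a was at -2.15 without knockout 1 and at -0.81 without WT 1, S100a4 at -0.21 without knockout 2, and Fn1 at -0.40 without knockout 1 and at 0.23 without knockout 2. Comp was at -0.44 without WT 3, Alpl at -0.48 without knockout 1 and at -0.09 without knockout 3, and Sox9 at -0.42 without knockout 1 and at 0.0010 without WT 3. The modulated list had mean log2 CPM, relative to its mean over the 6 libraries, of 0.57, -0.36 and 0.37 in WT 1, 2 and 3 and of 0.54, -0.67 and -0.45 in knockout 1, 2 and 3. Adventitial fibroblast markers, which share Lum, Dcn and Ly6a with the modulated list, were lower for 11 of 14 members without passing (adjusted p = 0.160; 0.0062 without WT 2 and 0.00054 without knockout 1), with relative means of 0.75, -0.62 and 0.23 in WT and 0.64, -0.61 and -0.39 in the knockout. Without WT 1 the contractile and modulated adjusted p were 0.929 and 0.502, without WT 3 they were 0.0685 and 0.266, without knockout 2 they were 0.525 and 0.592, and without knockout 3 they were 0.239 and 0.174. Over all alternatives the contractile p ranged from 9.2e-05 to 0.932, the modulated p from 1.6e-07 to 0.822 and the osteochondrogenic p from 5.5e-06 to 0.899. The osteochondrogenic p was 0.0564 without WT 2, 0.377 without WT 3, 0.116 without knockout 2 and 0.899 without knockout 3, and also 0.525 in DESeq2, 0.0509 after thinning and 0.0519 with the filter of 1 CPM. That filter gave 0.0519 for the contractile and 0.0507 for the modulated list. With 1 surrogate variable, which was positive in WT 1, WT 3 and knockout 1 and negative in the other libraries, the contractile, modulated and osteochondrogenic p were 0.932, 0.652 and 0.234, while the miR-21 target list (0.00036) and the MHC class II list (0.00023) still passed.

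Of the immune gene groups, MHC class II, cytokine and interferon genes lay lower in the knockout, while 8 of 11 macrophage markers were higher without passing (preset camera adjusted p = 0.432). All 7 MHC class II genes were lower (adjusted p = 1.4e-05; adjusted p = 0.567 with an estimated correlation), with H2-Eb1 at 5.40 ± 0.877 CPM in WT and 2.598 ± 1.13 CPM in the knockout (SD, n = 3 each), H2-Aa at a log2 fold change of -0.98 ± 0.47 and H2-DMb1 at -0.31 ± 0.14 (SE). Of 24 cytokine, chemokine and NF-kB genes, 21 were lower (adjusted p = 0.0129; adjusted p = 0.822 with an estimated correlation), with the alarmin Il33 at -1.55 ± 0.52, Cxcl2 at -0.96 ± 0.67 and the adhesion gene Sele at -0.98 ± 0.70. Of 21 interferon-stimulated genes, 18 were lower (adjusted p = 0.0129; adjusted p = 0.822 with an estimated correlation), with Gbp2 at -0.34 ± 0.24 and Ifit3 at -0.56 ± 0.58. The MHC class II list passed without each library in turn, although its relative mean log2 CPM in knockout 1 (0.28) lay among those of WT 1, 2 and 3 (0.21, 0.40 and 0.48) and not beside knockout 2 and 3 (-0.57 and -0.80). H2-Aa was at -1.76 without knockout 1 and H2-DMb1 at -0.19 without knockout 2. In the main edgeR fit no member of these 3 lists passed over all genes or adjusted over the list alone. With the replicate number as a block Il33 passed over all genes (edgeR adjusted p = 0.0178). The cytokine list had mean log2 CPM, relative to its mean over the 6 libraries, of 1.00, -0.73 and 0.31 in WT 1, 2 and 3 and of 0.68, -0.89 and -0.37 in knockout 1, 2 and 3. Its adjusted p was 0.468 without WT 1, 0.0756 without WT 3 and 0.454 without knockout 2. Without WT 1 the log2 fold changes of Cxcl2 and Sele were -0.36 and -0.23, without WT 2 that of Cxcl2 was -1.40, and without knockout 1 that of Sele was -1.83. The interferon list had relative means of 0.47, -0.64 and 0.57 in WT 1, 2 and 3 and of 0.57, -0.78 and -0.19 in knockout 1, 2 and 3, with knockout 1 the highest of the 6 libraries. Ifit3 was at -0.10 without WT 3 and at -1.20 without knockout 1, and Gbp2 at -0.15 without WT 1 and without knockout 2. The interferon p was 0.900 without WT 3, 0.454 without knockout 2, 0.166 in DESeq2 and 0.124 after thinning. With 1 surrogate variable the interferon list turned direction (0.927) and the cytokine p was 0.999. Over all alternatives the cytokine p ranged from 2.8e-09 to 0.999 and the interferon p from 9.5e-07 to 0.927.

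TGF-beta and BMP response genes were higher for 16 of 20 members (adjusted p = 0.0328; adjusted p = 0.567 with an estimated correlation). Ski passed adjusted over the list alone (0.0279), and Skil had a log2 fold change of 0.15 ± 0.07 (SE). The list shares Ski, Smad7 and Tgfbr2 with the miR-21 target list, so these lists are not independent. The adjusted p was 0.0663 without WT 1, 0.0564 without WT 2, 0.115 without knockout 1, 0.0796 without knockout 2 and 0.0604 in limma-voom with sample weights, and ranged from 0.0022 to 0.567 over all alternatives. Of 6 cardiac muscle markers, 5 were higher (adjusted p = 0.0048; adjusted p = 0.822 with an estimated correlation; 0.116 without knockout 2), and the calcium release channel gene Ryr2 (0.54 ± 0.08) and the actin gene Actc1 (1.44 ± 0.38) passed adjusted over the list alone. Myl4 had 0.41 ± 0.16 (SE). Ryr2 is also expressed in vascular smooth muscle. Immediate early and handling genes were higher for 16 of 17 members (adjusted p = 0.0048; adjusted p = 0.822 with an estimated correlation), with Atf3 at 0.54 ± 0.31, Fosb at 0.46 ± 0.27 and Nr4a1 at 0.36 ± 0.22. Without knockout 2 these were at 0.27, 0.27 and 0.16, and without WT 3 at 0.82, 0.76 and 0.52. Their adjusted p was 0.289 without WT 1, 0.053 without WT 2, 0.160 without knockout 2 and 0.0883 with 1 surrogate variable, and ranged from 1.3e-08 to 0.822 over all alternatives.

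**Figure D3:**
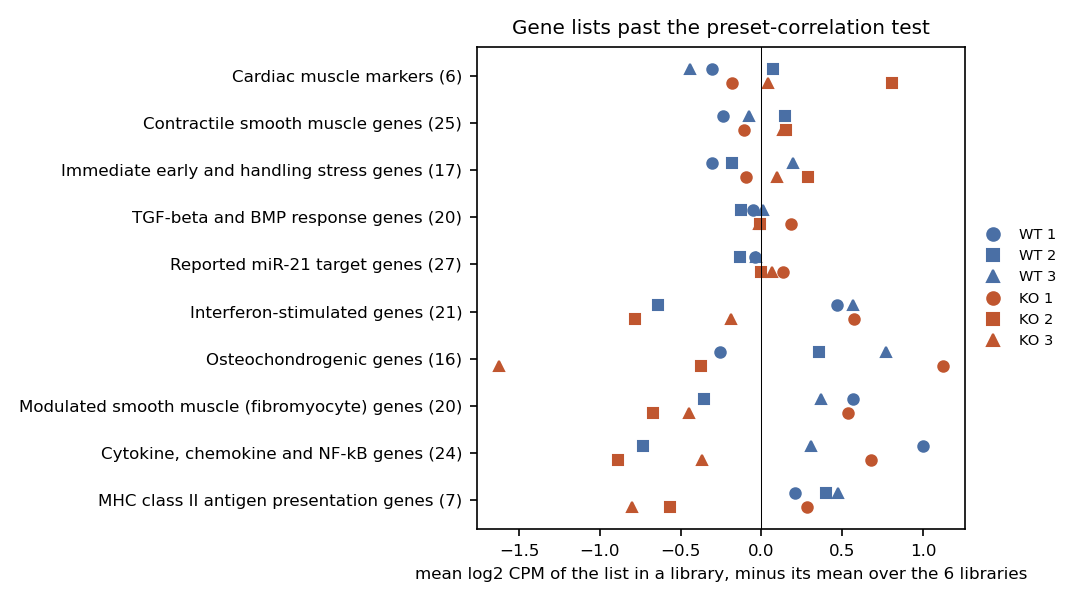
Mean log2 CPM of each list in each library minus its mean over the 6 libraries (x) for the 10 lists that passed with the preset correlation (y, tested members in parentheses), with WT in blue, knockout in orange and symbols for replicates 1, 2 and 3. In the cytokine list WT 2 lay at -0.73, on the side of knockout 2 and 3, and knockout 1 at 0.68, on the side of WT 1 and 3.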

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

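Thinning and the surrogate variable were chosen after seeing the data. The count of genes called was 0 in every alternative except the following. DESeq2's Wald test called 75 genes, and leaving out 1 library gave 0 to 1 (Moxd1, without knockout 1). The cause of the gap between tools was not tested. With the replicate number as a block 1 gene was called (Il33, lower) and 14 lists passed, with the matrix list at 0.00115, fibroblast at 0.0013, sterol efflux at 0.0022 and proteases at 0.0481 among them and the osteochondrogenic list at 0.125. Whether the numbers pair the samples stayed open. Same-numbered deviations correlated at 0.289 and 0.317 for numbers 1 and 2, above every other pair (at most 0.117, WT 2 with knockout 3). For number 3 the value was -0.026, and WT 3 correlated best with knockout 1 (0.066). The common dispersion was 0.0211 with the block and 0.0385 in the main fit.

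The number of lists past the threshold was 10 with the preset correlation and 0 with an estimated one. With 1 library left out it was 3 to 14 (3 without knockout 2), for reasons not tested. The estimated correlation was 0.0095 for the miR-21 targets, near the preset of 0.01, and -0.030 for the TGF-beta list. Correlated members thus do not account for the rise of the miR-21 list to 0.516. In the other lists of the 10 the estimate lay between 0.423 (cardiac) and 0.785 (interferon). If these estimates hold, the preset p of those lists is too small. The miR-21 target list and the MHC class II list each passed in 15 of 16 alternatives. The site difference kept its direction and a permutation p over genes under 0.05 in all alternatives run. With 1 library left out it ranged from 0.0448 to 0.0679. Its excess over permuted sites then ranged from 0.0247 (without WT 1) to 0.0379 (without knockout 3).

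Of 735 values of named genes under alternatives, 698 kept direction and side of the threshold, 18 passed it and 19 turned sign. Leaving out 1 library moved the fold change of 28 of the 49 named genes by over 1.5 times or turned its sign. For the 480 list values the numbers were 361 unchanged in both, 49 no longer past, 40 newly past and 30 turned. The causes were not tested. Fn1 turned with upper-quartile factors (-0.0074), limma-voom weights (-0.104) and the block (-0.0469), and Pdcd4 with limma-voom weights (-0.0233). With 1 surrogate variable Vmp1 was at 0.126, Tagln at -0.0676, Cnn1 at -0.119 and Pdcd4 at -0.0048. With 1 library left out the log2 fold change ranged from -0.0747 to 0.240 for Cnn1, -0.402 to 0.226 for Fn1, -0.105 to 0.175 for Pdcd4, -0.416 to 0.0010 for Sox9, -0.0583 to 0.153 for Tagln, -0.108 to 0.281 for Timp3 and -0.149 to 0.158 for Vmp1.

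Lists that turned direction had these adjusted p. Schwann markers had 0.821 without a filter, 0.431 in DESeq2, 0.932 thinned and 0.652 with the surrogate variable. Erythroid genes had 0.501 in DESeq2, 0.0419 with the block and 0.856 thinned. Cholesterol synthesis had 0.856 thinned and 0.665 with the surrogate variable, which also gave 0.652 for proteases, 0.927 for interferon, 0.932 for sterol efflux, 0.0565 for cell cycle, 0.927 for brown adipocyte and 0.932 for skeletal muscle. With 1 library left out the ranges were 0.266 to 0.826 for cholesterol synthesis, 0.0033 to 0.409 for circadian, 0.0366 to 0.819 for erythroid, 0.0640 to 0.871 for fatty acid oxidation, 0.0756 to 0.932 for glycolysis, 0.00056 to 0.871 for macrophage, 0.0302 to 0.988 for proteases and 0.297 to 0.988 for Schwann.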

Other observations

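The tests of UTR length and expression, of other sequences, of exchanged labels, of macrophage and endothelial transcripts, and the counts over splits for the site difference, the lists and edgeR were chosen after the result was seen.

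Of the other lists, 26 of 34 matrix genes were lower (preset camera adjusted p = 0.0546), as were 24 of 30 ribosomal protein genes (0.0628), 13 of 17 sterol efflux genes (0.0973) and 30 of 35 respiratory chain genes (0.0973). These did not pass with the main settings, nor did the lists that follow. The matrix list passed in 7 of 16 alternatives, among them DESeq2 (0.0395), limma-voom with sample weights (0.0432), no filter (0.0253), thinning (0.0409), without WT 2 (0.0021) and without knockout 1 (3.0e-05), and ranged up to 0.932. Respiratory chain and p53 genes passed in 4 alternatives each, ribosomal, sterol efflux, stress response, fibroblast, endothelial, protease and erythroid lists in 3 each, cell cycle and macrophage lists in 2 each, and circadian and fatty acid oxidation lists in 1 each. The test pointed down for the stress response list (0.108), fibroblast markers (0.160), fatty acid oxidation (0.194), cell cycle (0.194), proteases (0.516), glycolysis (0.516) and Schwann markers (0.851). It pointed up for the p53 list (0.108), circadian genes (0.127), endothelial markers (0.261), macrophage markers (0.432), skeletal muscle (0.517), white adipocyte (0.623), brown adipocyte (0.726), erythroid (0.748) and cholesterol synthesis (0.794). All 5 erythroid genes were lower by fold change although the list test pointed up, and the median, mean and test of the cholesterol, white adipocyte, brown adipocyte and Schwann lists also differed in sign. Adjusted over the list alone, Reck passed among the proteases (0.00115) and Plin4 among the white adipocyte markers (0.0417). Lymphocyte markers had 2 tested members, and the neutrophil and mitochondrially encoded lists were not analysed here. The clock output genes set WT 1 apart: Dbp was at 6.62 CPM there and between 77.7 and 225 CPM in the other libraries, and Nr1d1 at 97.5 CPM against 259 to 465. In WT 1, 2 and 3 Hba-a1 was at 84.9, 13.2 and 3.16 CPM and Hbb-bs at 151, 23.1 and 6.14 CPM. In knockout 1, 2 and 3 Hba-a1 was at 47.8, 13.1 and 4.55 CPM and Hbb-bs at 81.2, 24.4 and 11.6 CPM. Both genes thus fell from replicate 1 to replicate 3 in each group, and same-numbered libraries lay near each other. These genes alone do not decide whether the numbers pair the samples. Plin4, Dbp, Nr1d1, Hba-a1 and Hbb-bs were named after their values were seen.

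Genes with a miR-21 site lay higher in the knockout. UTR length and expression account for part of it, since permuted sites gave 0.0257 of the 0.0569, but not for the excess of 0.0312, and binning on UTR length and GC content left 0.0316. Of 359 other 7-base sequences of the same composition, 0 had an excess as large. The highest, TAAGCTA (0.0285) and AAGCTAT (0.0232), overlap the longer miR-21 site, so that GTACATA (0.0211) is the highest that does not. TAAGCTA is the longer site without its first base, so its excess is not a background value. The 10 splits of the 6 libraries are too few for a share under 0.05: 1 split, the real one, reached 0.0569, and the highest other size was 0.0356 (excess 0.0310 and 0.0226, the latter in another split). Loss of repression by miR-21 stays as a hypothesis. Among DESeq2's higher genes 12 of 54 searched held a site against 7.08% of other genes (Fisher's exact test, two-sided, p = 0.000343). Among its lower genes 1 of 14 searched held a site, against 7.14% of other genes. These calls come from the same 6 libraries as the site difference, so they are no separate support for it. Fisher's test treats genes as independent and takes no account of UTR length or expression.

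Genes near Mir21a on chromosome 11 differed more often than genes elsewhere. Within 5 Mb, 14 of 98 tested genes (14.3%) had an unadjusted edgeR p under 0.05, 7 higher and 7 lower, against 7.14% on the rest of the chromosome. Of windows of as many neighbouring genes elsewhere, 0.868% held as many, and the windows of 2.5 and 10 Mb gave 2.20% and 3.93%. Only 1 of the 14 genes held ATAAGCT, which argues against loss of repression through that site. Alleles of another strain carried along with the floxed gene may account for it, since the share and both directions are what they would give, but no genotype was read and an effect of the deletion itself stays open; Tspoap1, 1.18 Mb from Mir21a, had 0.0527, 0 and 0.0195 CPM in WT 1, 2 and 3 (2, 0 and 3 counts) and 0.858, 1.72 and 1.42 CPM in knockout 1, 2 and 3.

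The split of WT 1, WT 3 and knockout 1 against WT 2, knockout 2 and knockout 3 called 522 genes in edgeR and 1509 in DESeq2, far more than the real split (0 and 75), which points to a structure of the samples other than genotype. Depth does not account for it, since 564 genes were called after thinning. Exchanged labels of WT 2 and knockout 1 are argued against by the site difference, which was 0.0196 with them exchanged and 0.0569 as labelled (excess 0.0165 and 0.0310). Markers of macrophages (-1.02), endothelium (-0.85), fibroblasts (-1.08) and lymphocytes (-0.35, 2 genes) all moved the same way on the log2 scale. The contractile shift of 0.28 would need 17.8% of other cells, but Lyz2 reached at most 12.6 CPM and Cdh5 0.580 CPM. These low levels argue against macrophages or endothelium as the whole cause. Pecam1 stayed between 52.9 and 63.6 CPM on both sides of the split. It is 1 of 13 tested endothelial markers, whose median moved by -1.12, so its level decides nothing. Fibroblasts could still contribute, as could a different state of the smooth muscle, which was not tested: Lum, between 706 and 4108 CPM, Dcn and Ly6a are in both the fibroblast and the modulated lists.

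The 10 splits are also too few to test the other counts. As many lists as the real 10 passed in 7 splits (highest other 19), as many edgeR genes as the real 0 in all 10 (highest other 522), and as many DESeq2 genes as the real 75 in 2 (highest other 1509).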
